A study of Homo sapiens with 24 samples.

How the data were processed

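Total RNA of HT29 cells, an established line from a human colorectal adenocarcinoma, was measured on 24 Affymetrix expression arrays. The arrays form 12 groups of 2 replicates. At each of 24, 48 and 72 h there was a group given vascular endothelial growth factor (VEGF) at 100 ng/ml, a group given the VEGF vehicle, a group given platelet-derived growth factor (PDGF) at 100 ng/ml and a group given the PDGF vehicle. Per the labels' protocols, 100 ng of total RNA was amplified and labelled with an IVT kit that primes on the poly(A) tail. The labels give an RNA integrity number (RIN) between 8.8 and 9.9 for each sample. They do not say whether replicates were separate cultures, so every p-value here measures only the spread between these samples, which may be technical.

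The deposited values are log2 expression levels made by the authors with RMA in R 3.0.1, per the submitters' processing notes. RMA corrects the background of each array, makes the distributions of the arrays equal and summarises the probes of a probe set. It therefore removes any shift shared by all genes of an array and compresses small changes of dim probe sets. Other steps were not given in the sources used here. The normalized table held 49495 probe sets, 49395 were in the values deposited with the samples, and the largest difference between them over shared probe sets was 0. The normalized table was used. Its values ran from 5.81 to 14.79, with array medians between 7.05 and 7.13.

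Of the probe sets, 202 were controls (100 for ERCC transcripts and 102 others) and were left out of every test. Among the 49293 others, 44988 carried 1 gene symbol in the platform annotation, 1832 carried several and 2473 carried none. No gene was named from a probe set with several symbols. Symbols were looked up by gene number in a RefSeq table used for names only: 44961 entries matched and 0 symbols needed an update. Each gene was represented by its probe set with the highest mean over the 24 arrays, which left 18132 genes. The 23 background probe sets had means from 6.02 to 10.45, a range that follows their base composition, and 16385 genes had a mean at or below the top of it. Signal at these levels can hold a large share of background, so changes there can be understated. The number of arrays limits the precision: in the averaged effect of either factor the median half-width of the 95% confidence interval over genes was 0.103 on the log2 scale.

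Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts of the 12 group means and eBayes over all 24 arrays), with Benjamini-Hochberg adjustment within each contrast and an adjusted p threshold of 0.05. All 12 groups share 1 estimate of the spread because 2 replicates alone give too few degrees of freedom. The contrasts were each factor against its own vehicle, averaged over the 3 times and at each time, the VEGF effect minus the PDGF effect, the VEGF vehicle against the PDGF vehicle, 72 h against 24 h and 48 h against 24 h over both vehicles, and moderated F tests of whether each factor's effect changed over time. Adjusted p-values in the text come from limma unless another test is named. Errors after ± are standard errors of the log2 change from that fit, or standard deviations where SD is written.

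In all, 25 gene lists with 537 entries were fixed before the data were examined, of which 500 were measured. They cover VEGF and PDGF ligands and receptors, immediate-early and MAPK feedback genes, calcineurin-NFAT and other VEGF response genes, SRF and YAP cytoskeletal targets, FOXO targets repressed by PI3K-AKT, DNA replication, mitosis, hypoxia and glycolysis, cholesterol synthesis, unfolded protein and amino acid stress, heat shock, interferon response, NF-kB inflammation, p53 targets, epithelial junctions and keratins, mesenchymal transition, Wnt targets and intestinal stem cells, enterocyte differentiation, goblet and secretory cells, apoptosis and autophagy, ribosomal proteins, oxidative phosphorylation, and markers of fibroblasts, endothelium and leukocytes as other cell types. Lists were tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated per list and with fry. Adjustment was over the 25 lists of a contrast.

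The genes named in the text follow a rule set at the same point. For each averaged effect and for 72 h against 24 h it takes the 10 largest rises and the 10 largest falls among genes past the threshold with the same sign in all matched pairs of arrays (6 pairs for a factor, 4 for time). Where fewer pass, it is filled by the smallest unadjusted p, and these genes are said not to pass. Up to 3 genes were taken for each other contrast, up to 4 members for each list, and the ligands and receptors always. Genes named outside this rule are said to have been chosen after their values were seen.

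The replicate number marks a shared hybridisation day in the labels, so the numbers pair the samples. Deviations of replicate 1 from its group mean correlated between all 66 pairs of groups, with r across genes from 0.209 to 0.808 (median 0.428). Genes are not independent replicates in these values. The median was 0.669 within a time and 0.381 between times. The fit with the replicate number as a block was therefore run for every result, and a fit with a block within each time was added after the arrays were seen to differ between days by an amount that depended on the time.

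The steps were tested on simulated data in which, among the 18132 genes, 67 changed 1.2-fold, 67 changed 1.5-fold and 66 changed 2-fold, with levels drawn from the means and spread of the real arrays with noise independent between genes. Without a block, changes of 1.2-fold, 1.5-fold and 2-fold were called for 59.7%, 97.0% and 98.5% of the changed genes in the averaged VEGF effect and for 58.2%, 92.5% and 98.5% in the averaged PDGF effect. In the PDGF effect at 72 h these shares were 7.46%, 80.6% and 95.5%. For 72 h against 24 h they were 50.7%, 95.5% and 100%. At most 4 unchanged genes were called in any of these fits. Real probe sets of related genes move together, which the simulation leaves out. For 72 h against 24 h the simulated levels kept only the mean of each replicate. Differences between the days that depend on the time were thus absent, and the count of unchanged genes called does not cover them.

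The alternatives tried were both blocks, only the arms compared, both vehicles pooled, each hybridisation day alone, RIN as a covariate, array weights, a trended and robust spread, a common array median, renewed quantile normalization, the mean of a gene's probe sets, all probe sets, genes at or above the median level or the median spread, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.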

Results

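Expression was measured in HT29 cells, a line derived from a human colorectal adenocarcinoma, on 24 arrays after 24, 48 or 72 h with VEGF, PDGF or the vehicle of either factor. VEGF and PDGF are secreted growth factors that signal through receptor tyrosine kinases, mainly on endothelial cells and on fibroblasts and other mesenchymal cells. The series set out to compare each factor with its vehicle in this epithelial cancer line. Each of the 12 groups had 2 arrays, 1 per hybridisation day, and replicates correlated across genes with r between 0.991 and 0.996, a value over genes that are not independent replicates. Median array levels lay between 7.05 and 7.13 on the log2 scale.

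Among the receptors of both factors, mean log2 levels were 6.39 for FLT1, 6.84 for KDR, 7.70 for FLT4, 7.81 for NRP1, 6.72 for NRP2, 6.50 for PDGFRA and 6.85 for PDGFRB. These lay inside the 6.02 to 10.45 range of the arrays' background probe sets. That range follows base composition, so its top is no detection limit, and these levels alone do not show whether the receptors were expressed. The ligand gene VEGFA had a mean of 10.48, just above that range, while PDGFC (9.42) and PDGFA (8.17) lay inside it. Markers of other cell types also lay inside it, with means of 6.61 for the fibroblast collagen COL1A2 and 7.11 for the endothelial adhesion gene PECAM1.

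Time and replicate, not the factors, ordered the arrays. The first principal component held 47.7% of the variance, and the sampling time accounted for 92.8% of it. The second held 20.7%, of which the replicate accounted for 92.1%. Replicate and hybridisation day are the same in the labels, so their shares cannot be told apart. The treatment arm accounted for 0.275% of the first component and 0.421% of the second.

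**Figure D1:**
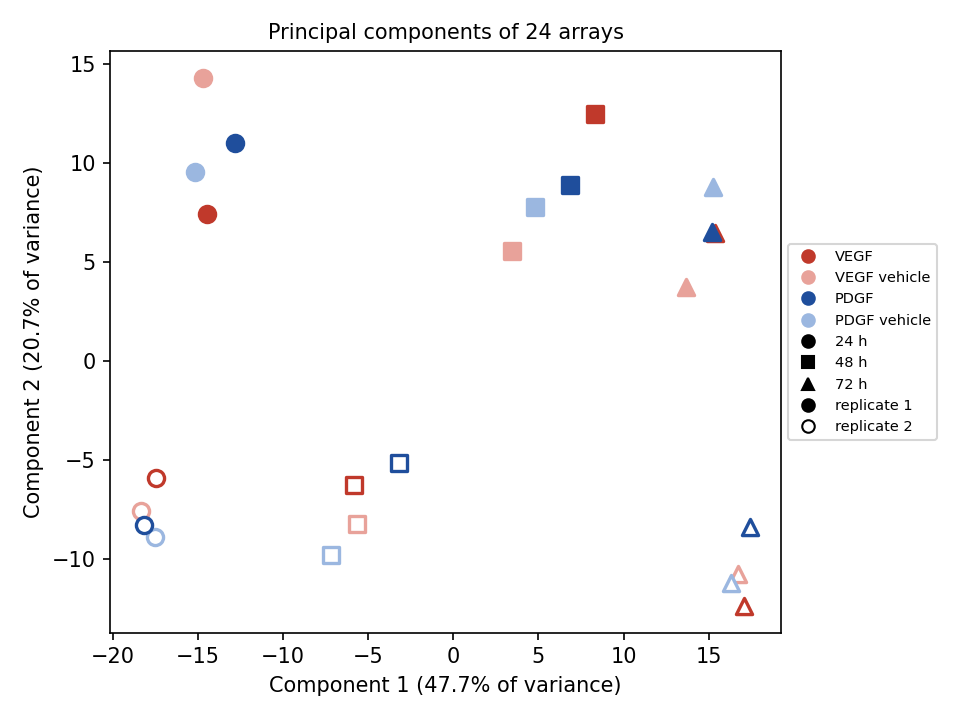
Principal components of the 24 arrays over the tested genes, with component 1 (47.7% of the variance) on the horizontal axis and component 2 (20.7%) on the vertical axis. Colours mark the 4 arms, shapes the 3 times, and filled or open symbols the replicate, which is the hybridisation day. Times separate along component 1 and replicates along component 2, while the arms of a time and replicate lie together.

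The first question was which genes VEGF changed. Averaged over the 3 times, 0 of 18132 genes passed limma's threshold, with 6 VEGF arrays against 6 of its vehicle. The gene closest to passing among those higher in every pair was ELSPBP1, a sperm-binding protein gene of the epididymis with a mean level of 6.72, at 0.12 ± 0.03 (limma's unadjusted p = 0.000992, adjusted p = 1.00, higher in 6 of 6 pairs). DNAAF9 followed at 0.14 ± 0.04 and FPR1, a formyl peptide receptor of neutrophils, at 0.11 ± 0.03. On the other side PHRF1, a ubiquitin ligase gene, stood at -0.09 ± 0.03 and GEMIN6, part of the complex that assembles spliceosomal particles, at -0.14 ± 0.04, both lower in 6 of 6 pairs and neither passing. The small nucleolar RNA gene SNORA33 had the largest difference of this kind, -0.22 ± 0.08.

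Unadjusted p lay under 0.05 for 362 genes, or 2.00%, fewer than the 5% expected by chance. The fit without a block leaves differences between the days in the spread, so it tends to call too few genes. With the replicate block limma gave 0 calls and 444 such genes (2.45%), and with the block within each time 0 calls and 632 (3.49%). Each day alone also gave 0 calls, with 476 such genes on the first and 1407 on the second. On leaving out 1 array the 362 became 221 (without the 24 h VEGF array of replicate 2) to 764 (without the 24 h vehicle array of replicate 1). The largest change of any gene was 0.34 on the log2 scale. The 95% interval lay inside a 1.5-fold change for 18076 genes (99.7%) and inside a 2-fold change for 18123. These intervals bound the measured change, which background can understate in dim genes. Changes measured on each hybridisation day correlated with r = -0.216 across genes, which are not independent replicates, and 45.0% of genes had the same sign on both days.

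Lists of genes known to respond to growth factor signalling did not pass after VEGF at the sampled times. Immediate-early genes respond within minutes and the first arrays are of 24 h, so a response over by then could not be seen. Of 26 immediate-early and MAPK feedback genes, which receptor tyrosine kinases induce through ERK, 0 passed over all genes and 0 adjusted over the list alone, with a median of -0.01 (camera adjusted p = 0.678). The best placed was DUSP4, an ERK phosphatase, at 0.08 ± 0.07. Of 16 calcineurin-NFAT genes the closest to passing was ADAMTS9 at 0.08 ± 0.04 (list adjusted p = 0.788), and FOXO targets repressed by PI3K-AKT had a list adjusted p of 0.788. VEGFA itself differed by 0.18 ± 0.15, with 0.49 on the first day and -0.13 on the second.

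With camera, 4 of the 25 lists passed, each with a small shift and with 0 members past the threshold over all genes or adjusted over the list alone. RIN in replicates 1 and 2 was 8.8 and 9.0 with VEGF against 9.2 and 9.5 with its vehicle at 24 h. It was 9.4 and 9.5 against 9.8 and 9.6 at 48 h, and 9.7 and 9.6 against 9.9 and 9.6 at 72 h. The lists were not tested with RIN as a covariate. Heat shock genes, which encode protein-folding chaperones, had a median of -0.08 (adjusted p = 0.00938), mitosis genes -0.06 (0.00949), DNA replication genes -0.04 (0.00949), and the 16 ligands and receptors 0.03 (0.0239). The estimated correlation gave adjusted p = 0.202 for the heat shock genes, 0.963 for the mitosis genes, 0.963 for the DNA replication genes and 0.202 for the ligands and receptors. Examples were BAG3 at -0.09 ± 0.07, CCNB1 at -0.13 ± 0.15, MCM10 at -0.08 ± 0.06 and NRP2 at 0.09 ± 0.03. The other lists had adjusted p between 0.103 and 0.984. Among these the SRF and YAP targets had a median of 0.01 and a mean of -0.01. NF-kB, p53, apoptosis and ribosomal genes had a median and mean at or above 0 while camera placed them down.

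Leaving out 1 array ended each of these 4 calls. Without the 48 h VEGF array of replicate 1 the adjusted p was 0.117 for heat shock and for mitosis genes, 0.192 for DNA replication genes and 0.179 for the ligands and receptors, and without the 24 h vehicle array of replicate 2 it was 0.0657, 0.977, 0.0657 and 0.0657. Of the 12 such fits the call ended in 3 for heat shock (the highest, 0.297, without the 48 h vehicle array of replicate 1), 6 for mitosis, 6 for DNA replication (0.708 without the 72 h vehicle array of replicate 1) and 8 for the ligands and receptors (0.184 without the 48 h vehicle array of replicate 2). The remaining arrays that ended a call were the VEGF arrays of 24 h (0.357 for mitosis genes without replicate 1, 0.340 for DNA replication genes without replicate 2), replicate 2 of VEGF at 72 h (0.970 for mitosis genes), replicate 1 of the vehicle at 24 h (0.0730 for the ligands) and replicate 2 of the vehicle at 72 h (0.0546 for the ligands). The number of lists past the threshold ran from 0 without the 24 h vehicle array of replicate 2 to 7 without the 48 h VEGF array of replicate 2.

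At single times VEGF again gave 0 calls, with 247, 282 and 563 genes at an unadjusted p under 0.05 at 24, 48 and 72 h. On leaving out 1 array these numbers ran from 325 to 901 (the highest without the vehicle array of replicate 2), from 187 to 1460 (the highest without the VEGF array of replicate 2, with a smallest adjusted p of 0.0774) and from 367 to 689. The genes closest to passing were SRGAP1, a GTPase-activating protein of the Slit-Robo pathway, at 0.26 ± 0.06 at 24 h, the secreted glycoprotein gene OLFM1 at -0.25 ± 0.07 at 48 h, and SHISA9 at 0.20 ± 0.04 at 72 h. The F test of a change of the VEGF effect over time gave 0 calls and 298 genes at an unadjusted p under 0.05, with 210 to 939 on leaving out 1 array and 1489 with the replicate block within each time (smallest adjusted p = 0.0770). LOC151760 (F = 13.0), the sulfate transporter gene SLC26A1 (F = 9.64) and the homeobox gene HOXB2 (F = 8.94) came closest. Camera on the lists at single times, added after seeing the data, passed 0, 4 and 4 lists at 24, 48 and 72 h (3, 5 and 5 with the replicate block) and 0 at each time with an estimated correlation.

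For PDGF, averaged over the times, 0 of 18132 genes passed in limma, with 6 arrays against 6. TFF3, the trefoil peptide of goblet cells, was lower in 6 of 6 pairs at -0.21 ± 0.07 without passing (unadjusted p = 0.00903, adjusted p = 1.00). The other genes closest to passing on that side were the histone gene H2BC15 at -0.11 ± 0.03, PPRC1, a coactivator of mitochondrial gene expression, at -0.13 ± 0.04, and the zinc finger gene ZNF551 at -0.17 ± 0.05. On the higher side SNTG1, a syntrophin, stood at 0.13 ± 0.03, the noncoding LINC02842 at 0.13 ± 0.03 and the phosphodiesterase PDE2A at 0.11 ± 0.03.

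An unadjusted p under 0.05 was found for 215 genes (1.19%, again below the 5% expected by chance). With the replicate block limma gave 0 calls and 325 such genes, and with the block within each time 0 calls and 680. Each day alone also gave 0 calls, with 276 such genes on the first and 916 on the second. The largest change of any gene was 0.42. The 95% interval lay inside 1.5-fold for 18066 genes (99.6%) and inside 2-fold for 18123, again a bound on the measured change, which can be understated in dim genes. Between the days the PDGF changes correlated with r = 0.0912 across genes.

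The 26 immediate-early and MAPK feedback genes had a median of 0.04 after PDGF and 0 members past the threshold (camera adjusted p = 0.511, 0 adjusted over the list alone). Here too a response over by 24 h could not be seen. VEGFA differed by 0.18 ± 0.15 and PDGFA by 0.03 ± 0.07. With camera, 3 lists passed, again with 0 members called over all genes or over the list alone. Ribosomal protein genes had a median of 0.07 (adjusted p = 1.58e-09) with RPS19 at 0.09 ± 0.05 and RPS18 at 0.09 ± 0.05. Unfolded protein and amino acid stress genes had a median of 0.09 (0.00162), with HERPUD1, a gene of endoplasmic reticulum degradation, at 0.13 ± 0.06, the serine synthesis gene PSAT1 at 0.15 ± 0.10 and the stress-induced SESN2 at 0.32 ± 0.22. Fibroblast markers, genes of another cell type, had a median of 0.04 (0.00119), with COL6A3 at 0.07 ± 0.03 from a mean level of 6.64. The estimated correlation gave adjusted p = 0.719 for the ribosomal genes, 0.519 for the stress genes and 0.230 for the fibroblast markers, and the stress list also missed the threshold without the 24 h vehicle array of replicate 2 (0.0846). The number of lists rose from 3 to 5 without the 48 h vehicle array of replicate 1, the 72 h vehicle array of replicate 2 or either 72 h PDGF array. The other lists had adjusted p from 0.282 to 0.900. Interferon genes (median -0.01) and leukocyte markers (median -0.01, mean 0.00) were placed up by camera.

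Single times after PDGF gave 0 calls in limma, with 169, 180 and 754 genes at an unadjusted p under 0.05, and with 130 to 236, 194 to 375 and 444 to 898 on leaving out 1 array. At 72 h PEAK1, a pseudokinase scaffold of the actin cytoskeleton, stood at -0.38 ± 0.07 (unadjusted p = 0.00012) and the neutral amino acid transporter gene SLC6A19 at 0.36 ± 0.07. The closest at the earlier times were CD226 at -0.22 ± 0.06 at 24 h and FOXI3 at -0.23 ± 0.05 at 48 h. The F test of a change over time gave 0 calls, 349 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.774, for SLC6A19, with 210 to 390 such genes on leaving out 1 array (the lowest without the 72 h PDGF array of replicate 2) and 985 with the block within each time. Camera passed 2, 5 and 0 lists at 24, 48 and 72 h, also added after seeing the data (2, 8 and 0 with the replicate block), and 0 at each time with an estimated correlation. With a replicate block within each time, 0 genes were higher and 3 lower at 72 h. These were the spliceosome-associated SRRM2 at -0.87 ± 0.38 (adjusted p = 0.0113 with that block), NBEAL1 at -0.41 ± 0.15 (0.0299) and PEAK1 (0.0299). SRRM2 and NBEAL1 were chosen after their values were seen. All 3 had an adjusted p of 1.00 without the block and of 0.388 or more with the simple replicate block.

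**Figure D2:**
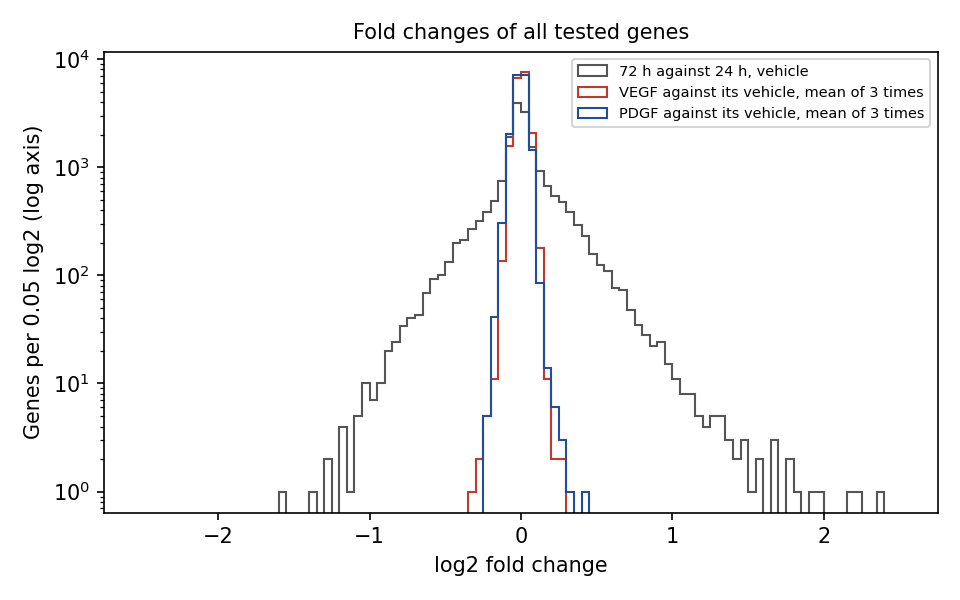
Number of genes per log2 fold change bin (log vertical axis) for the 18132 tested genes in 3 comparisons. Both factors lie within 0.42 of 0 on the log2 scale, while 72 h against 24 h in vehicle arrays reaches 2.36 upward and -1.57 downward.

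The effects of the factors were also compared with each other. LINC02842 differed by -0.21 ± 0.05 between the VEGF and the PDGF effect, FOXI3 by 0.18 ± 0.04 and the ciliary dynein gene DNAI1 by 0.15 ± 0.04. None passed: limma gave 0 calls, 185 genes at an unadjusted p under 0.05 (132 to 296 on leaving out 1 array), and an interval inside 1.5-fold for 17924 genes. The vehicles of both factors differed in 0 genes, with 161 at an unadjusted p under 0.05 (136 to 488 on leaving out 1 array, the highest without the 24 h VEGF vehicle array of replicate 2). PEAK1 came closest at -0.14 ± 0.04, followed by KRTAP17-1 at 0.09 ± 0.03 and the microtubule-associated MAP6 at 0.11 ± 0.03.

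Time in culture changed far more genes. From 24 to 72 h in the vehicle arrays, with 4 arrays at each time, 2275 genes rose and 1560 fell, and 90 changed more than 2-fold. The 4 arrays are both vehicles on each of 2 days, and groups of the same time shared their deviations between days (median r 0.669). They are not 4 independent samples, so p-values of the time comparisons, those at 48 h included, can be too small. With each array set to a common median, 1837 rose and 1905 fell, so the share of rises was 49.1% in place of 59.3%. LCN2, the secreted iron-siderophore binding protein lipocalin, rose by 2.36 ± 0.36 (adjusted p = 0.000259), from a log2 level of 9.91 to 12.27. ASNS, which makes asparagine, rose by 2.16 ± 0.30 (adjusted p = 0.000102), from 10.80 to 12.96. CAV1, the membrane scaffold of caveolae, fell most, by 1.57 ± 0.15 (adjusted p = 5.24e-06), from 10.69 to 9.12. All changes named here had the same sign in 4 of 4 pairs of arrays matched on vehicle and replicate unless another count is given.

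Other large rises were found in single genes of several functions. ASS1, which makes argininosuccinate, rose by 1.96 ± 0.29, PHGDH, the entry enzyme of serine synthesis, by 1.69 ± 0.28, and mitochondrial PCK2 by 1.67 ± 0.32. The stress-induced genes NIBAN1, TRIB3 and NUPR1 rose by 2.22 ± 0.34, 1.84 ± 0.38 and 1.76 ± 0.43. The monocarboxylate transporter family gene SLC16A4 rose by 1.91 ± 0.25 and the cholesterol exporter ABCG1 by 1.75 ± 0.15. Adjusted p for these 8 genes lay between 3.07e-06 and 0.00709.

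Beside CAV1, the largest falls were in the noncoding DLEU2 (by 1.27 ± 0.13), BRI3BP (by 1.18 ± 0.17), the proprotein convertase PCSK5 (by 1.18 ± 0.26), the cell cycle phosphatase CDC25A (by 1.16 ± 0.11), the RNA polymerase III subunit POLR3K (by 1.14 ± 0.09) and the spindle gene HAUS7 (by 1.09 ± 0.13), all with adjusted p of 0.00343 or less. Other probe sets of DLEU2 and POLR3K changed by as little as -0.00 and -0.05. The aldo-keto reductases AKR1B15 and AKR1B10 fell by 1.36 ± 0.32 (adjusted p = 0.00533) and 1.30 ± 0.37 (0.0197), and are uncertain as separate results because such near-identical copies can share probe signal. CAV2, the partner of CAV1, fell by 1.18 ± 0.32 (0.0139). The calls of AKR1B10 and CAV2 ended on leaving out the 72 h array of replicate 1 or the 24 h array of replicate 2 of either vehicle, with adjusted p from 0.0538 to 0.0900 and from 0.0546 to 0.0674.

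DNA replication genes fell almost as a whole: 29 of 32 fell over all genes, 0 rose and 32 fell adjusted over the list alone, with a median of -0.84 (camera adjusted p = 2.19e-23, adjusted p = 0.128 with an estimated correlation). GINS2 of the replicative helicase fell by 1.07 ± 0.13, the maintenance methylation factor UHRF1 by 1.02 ± 0.11, the replication initiation factor MCM10 by 1.01 ± 0.08 and MCM3 by 0.98 ± 0.12. Mitosis genes were less uniform: 3 of 30 fell and 0 rose (1 adjusted over the list alone), with a median of -0.29 (adjusted p = 0.00058, adjusted p = 0.684 with an estimated correlation). The proliferation marker MKI67 fell by 0.85 ± 0.18 (adjusted p = 0.00266). The other calls, CDC20 and CCNA2 (the latter lower in 3 of 4 pairs), ended in 6 and 4 of the 8 fits that left out 1 array. The list median was 0.11 on the first day and -0.71 on the second. The list call ended without the 24 h VEGF vehicle array (0.0710) or the 72 h PDGF vehicle array (0.0504) of replicate 2. Heat shock genes fell in 5 of 12 cases, 5 also adjusted over the list alone, with a median of -0.22 (adjusted p = 0.00428, adjusted p = 0.128 with an estimated correlation). Among them the chaperone genes HSPH1, HSP90AA1 and HSPE1 fell by 0.85 ± 0.10, 0.80 ± 0.11 and 0.74 ± 0.08. Cholesterol synthesis genes fell in 12 of 17 cases (13 adjusted over the list alone, median -0.31, adjusted p = 1.28e-07, adjusted p = 0.128 with an estimated correlation), among them ACAT2 by 0.77 ± 0.15, IDI1 by 0.76 ± 0.17 and the squalene epoxidase SQLE by 0.65 ± 0.10.

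Interferon response genes rose in 17 of 26 cases and fell in 0, with 17 also adjusted over the list alone. Their median was 0.37 (camera adjusted p = 1.28e-07), and the call held with an estimated correlation (adjusted p = 0.00123, and 0.00817 with the replicate block). IFI35 rose by 0.69 ± 0.08, the RNA-sensing synthetase OAS1 by 0.69 ± 0.09, the RNA sensor RIGI by 0.52 ± 0.07 and the antiviral GTPase MX1 by 0.50 ± 0.06. The list of FOXO targets, which AKT signalling represses, also passed, with 11 of 18 rising and 0 falling over all genes and over the list alone (median 0.56, adjusted p = 4.7e-07, adjusted p = 0.0201 with an estimated correlation). That second value missed the threshold with the replicate block (0.0655) or the block within each time (0.0856). YPEL5 rose by 1.32 ± 0.11, KLHL24 by 1.30 ± 0.15 and YPEL3 by 0.64 ± 0.07. The receptor gene ERBB3 rose by 0.65 ± 0.08, with 1 of its 3 probe sets at -0.22.

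Unfolded protein and amino acid stress genes rose in 14 of 24 cases and fell in 2, with 14 and 4 adjusted over the list alone (median 0.58, adjusted p = 0.00058, adjusted p = 0.129 with an estimated correlation). HERPUD1 rose by 1.02 ± 0.07 and PSAT1 by 0.93 ± 0.12. Apoptosis and autophagy genes rose in 6 of 19 cases and fell in 2 (8 and 2 adjusted over the list alone, median 0.21, adjusted p = 0.0189, adjusted p = 0.128 with an estimated correlation). They included the autophagy gene WIPI1 at 0.83 ± 0.13 and the initiator caspase CASP9 at 0.46 ± 0.07. This list's call ended without the 24 h VEGF vehicle array of replicate 1 (0.0576). Ribosomal protein genes rose in 4 of 22 cases (3 adjusted over the list alone, median 0.14, adjusted p = 0.00058, adjusted p = 0.581 with an estimated correlation). Their highest call, RPL3 at 0.28 ± 0.07, had 1 of 3 probe sets at -0.13 and missed the threshold without the 24 h PDGF vehicle array of replicate 2 (0.0503). Without that array the other calls, RPL13, RPS6 and RPS9, also ended, and over the 8 fits that left out 1 array they ended in 3, 5 and 7.

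**Figure D3:**
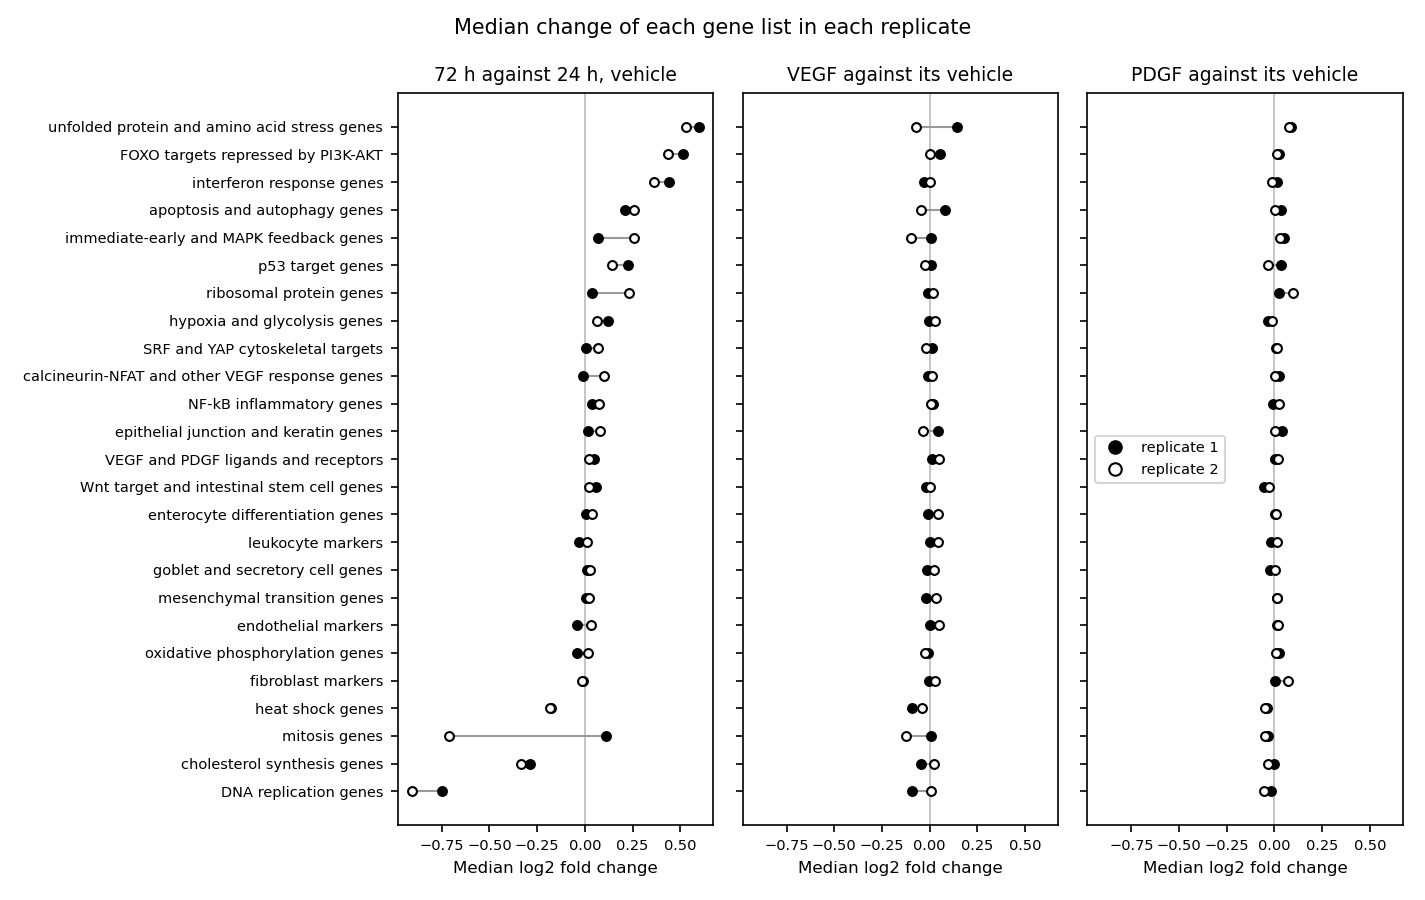
Median log2 fold change of each of the 25 gene lists on the first hybridisation day (filled, replicate 1) and on the second (open, replicate 2) for time and for each factor. For 72 h against 24 h the DNA replication list lies at -0.75 and -0.91 and the mitosis list at 0.11 and -0.71, while for a factor the list median farthest from 0 is 0.14, that of the stress genes after VEGF on the first day.

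The other lists did not pass as lists between 24 and 72 h, though some members did. Of the 16 ligands and receptors 2 rose and 0 fell: VEGFA by 1.15 ± 0.18 (adjusted p = 0.000334), from 9.77 to 10.93, and VEGFB by 0.31 ± 0.06 (0.00139), with a list median of 0.02 (adjusted p = 0.275). PDGFA stood at 0.23 ± 0.08 (adjusted p = 0.0554, and 0.0257 with the replicate block). Hypoxia and glycolysis genes rose in 7 and fell in 4 of 22 cases (8 and 4 adjusted over the list alone, median 0.13, adjusted p = 0.138), with NDRG1 up by 1.46 ± 0.20, the collagen hydroxylase P4HA2 up by 0.93 ± 0.15 and PFKP down, at -0.28 ± 0.05. Of 16 p53 targets 6 rose and 1 fell (7 and 2 adjusted over the list alone, median 0.19, adjusted p = 0.0738, and 0.0296 with the replicate block, or 0.358 with the block and an estimated correlation). The pro-apoptotic BBC3 rose by 0.90 ± 0.08 and the nuclease AEN fell by 0.46 ± 0.08. TP53INP1 rose by 0.88 ± 0.05, though its other probe set stood at -0.06. Immediate-early and MAPK feedback genes rose in 3 of 26 cases and fell in 0 (median 0.20, adjusted p = 0.211, and 0.0134 with the replicate block, or 0.358 with the block and an estimated correlation), among them ETV5 by 0.56 ± 0.13 and ETV4 by 0.35 ± 0.07.

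Differentiation and adhesion genes moved singly. Of 20 goblet and secretory genes 2 rose and 0 fell (median 0.01, adjusted p = 0.372): TFF3 by 0.92 ± 0.09 and SPINK4 by 0.88 ± 0.12. Enterocyte genes rose in 3 and fell in 1 of 28 cases (median 0.02, adjusted p = 0.588), with CEACAM1 up by 1.00 ± 0.11, the fatty acid binding FABP1 up by 0.38 ± 0.06 and CEACAM6 at -0.62 ± 0.15. Epithelial junction and keratin genes rose in 4 of 20 cases (median 0.02, adjusted p = 0.372), with CLDN1 up by 0.63 ± 0.14, the splicing factor ESRP1 by 0.62 ± 0.11 and CLDN7 by 0.55 ± 0.10. Mesenchymal transition genes rose in 3 and fell in 1 of 20 cases (median -0.00, mean 0.02, adjusted p = 0.889), with the matrix glycoprotein TNC falling by 0.86 ± 0.06 and TGFBI rising by 0.67 ± 0.13. Of 18 Wnt and stem cell genes 2 rose and 1 fell (1 and 1 adjusted over the list alone, median 0.02, adjusted p = 0.538): PROM1 rose by 0.41 ± 0.07 and the stem cell receptor LGR5 fell by 0.68 ± 0.15. Of 19 SRF and YAP targets 5 rose (median 0.13, adjusted p = 0.102), FHL2 by 0.47 ± 0.12 and the tropomyosin TPM1 by 0.27 ± 0.05. Of 20 NF-kB genes 4 rose (median 0.07, adjusted p = 0.0828), led by LCN2. The calcineurin-NFAT list had 1 rise and 1 fall in 16 (median 0.08, adjusted p = 0.579), the fall being that of tissue factor, F3, by 0.45 ± 0.08. Oxidative phosphorylation genes rose in 1 and fell in 5 of 24 cases (2 and 7 adjusted over the list alone, median -0.02, adjusted p = 0.211), ATP5MC1 by 0.57 ± 0.11. Fibroblast, endothelial and leukocyte markers had 0 calls among 12, 12 and 11 genes, with medians of -0.03, -0.01 and 0.01 and adjusted p of 0.372, 0.774 and 0.926; camera placed the leukocyte list down.

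Between the days the changes of all genes from 24 to 72 h correlated with r = 0.771, and 67.1% of all genes had the same sign on both, while the mitosis list median differed by day. In the 8 treated arrays of 24 and 72 h, which share no array with the vehicle comparison, 3809 of the 3835 had the same sign and 3068 were also called with it, with r = 0.933 across all genes. They share its replicates and hybridisation days, so differences between the days that depend on the time enter both comparisons. The treated arrays are therefore no independent repeat. The naming rule chose 97 genes that passed here, some of them only counted above, and 82 kept their call in all 8 fits that left out 1 array. Among those only counted, ICAM1 lost it in 7 of the 8 fits, JUP and SP5 in 5, RCAN1, RELB and VIL1 in 4 and SPRY1 in 3. Another probe set changed far less than the one reported for UHRF1 (-0.05), NDRG1 (0.09), HERPUD1 (0.10), VEGFA (0.11), TNC (-0.13), ETV5 (0.07), CLDN1 (0.08), LGR5 (-0.09), CDC20 (-0.09), TPM1 (0.04), CEACAM1 (0.15), CASP9 (0.15) and NIBAN1 (0.35). It had the other sign for RPS6 (-0.06), RCAN1 (-0.04) and VIL1 (-0.15), and among genes only counted for TNFAIP2 (-0.08), MMP14 (-0.11) and GABARAPL1 (-0.11).

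**Figure D4:**
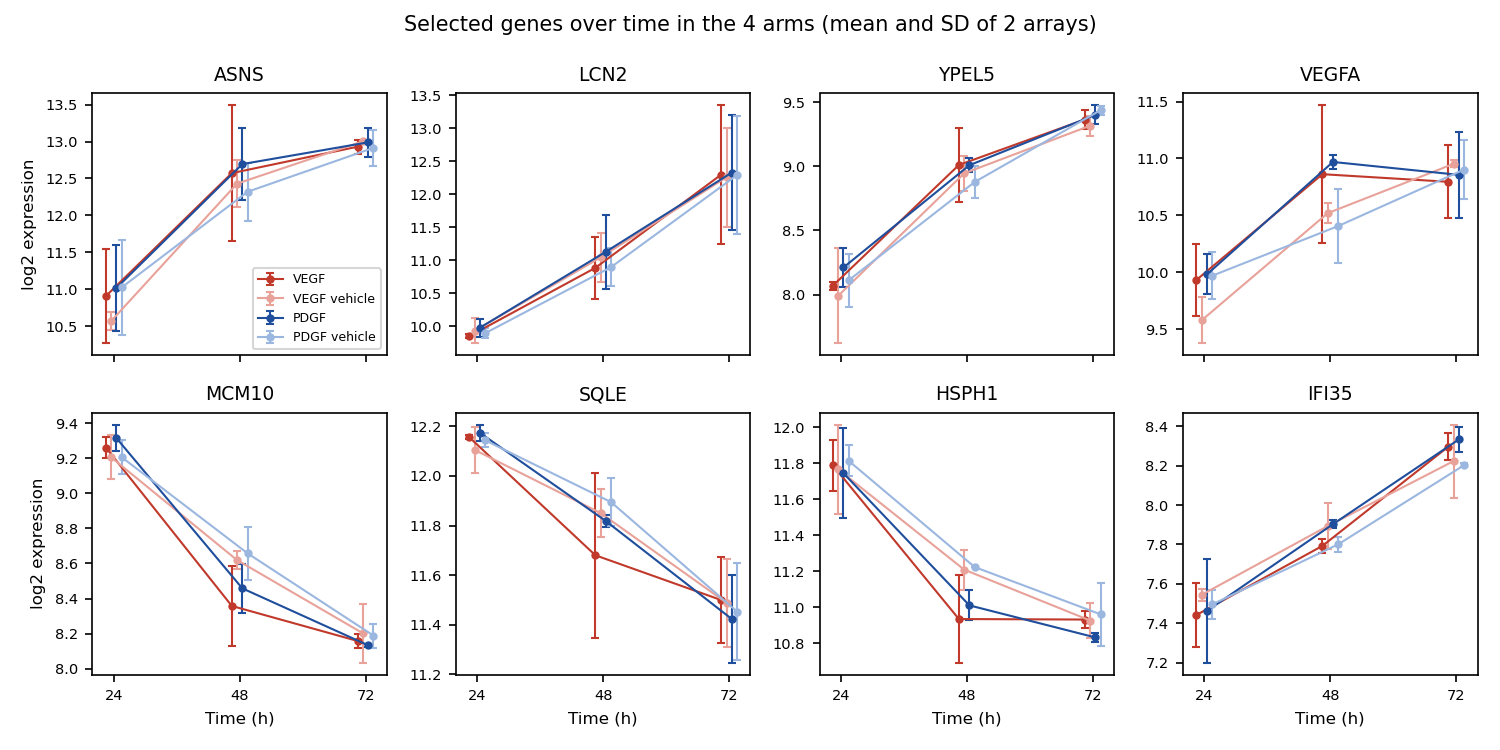
Log2 expression of 8 genes against time in the 4 arms, with points at the mean and bars at the SD of 2 arrays. ASNS, LCN2, YPEL5, VEGFA and IFI35 lie higher and MCM10, SQLE and HSPH1 lower at 72 h than at 24 h in each of the 4 arms.

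By 48 h part of this change was present. Against 24 h, 290 genes rose and 283 fell, and with a common array median 182 rose and 315 fell. DEPTOR, an inhibitor of the mTOR kinase, rose by 1.18 ± 0.12 (adjusted p = 0.000281), and GEMIN5, which delivers RNA to the spliceosome assembly complex, fell by 0.66 ± 0.08 (0.00123). DLEU2 fell by 0.76 ± 0.13 (0.00551), with 1 of its 3 probe sets at 0.04. ASNS rose by 1.58 ± 0.30 (0.00919), a call that ended with RIN as a covariate (0.0555) or without the 48 h array of replicate 1 of the VEGF vehicle (0.0547) or the PDGF vehicle (0.0536). CAV1 fell by 0.76 ± 0.15 (0.0113) and lost its call without the same arrays (0.0685 and 0.0660) or in a fit of vehicle arrays alone (0.0630). SLC16A4, at 1.08 ± 0.25 (0.0278), lost it in that fit (0.0730) and in each of the 8 fits that left out 1 array (0.0537 to 0.106).

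In the lists at 48 h, 5 DNA replication genes fell (17 adjusted over the list alone, median -0.36, camera adjusted p = 2.77e-16), 5 FOXO targets rose (median 0.25, 3.88e-06), 4 stress genes rose (median 0.31, 0.000307), 1 heat shock gene fell (median -0.14, 0.000307) and 2 apoptosis and autophagy genes rose (median 0.09, 0.0115). The estimated correlation gave adjusted p = 0.140 for the DNA replication, stress and apoptosis lists, 0.0574 for the FOXO targets and 0.0957 for the heat shock genes. The replicate block raised the count of lists past the threshold from 5 to 9, and 0 passed with the block and an estimated correlation. From 48 to 72 h, a comparison added after seeing the data, 9 interferon response genes rose (median 0.31, adjusted p = 0.00017 with an estimated correlation).

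The number of genes called at 48 h moved with the model. RIN in replicates 1 and 2 was 9.2 and 9.5 at 24 h and 9.8 and 9.6 at 48 h for the VEGF vehicle. For the PDGF vehicle it was 9.6 and 9.6, then 9.8 and 9.7. RIN as a covariate lowered the count, as given below with the other alternatives. The replicate block gave 1749 calls, and the first and second hybridisation days alone gave 2507 and 1026. Leaving out replicate 1 of the 24 h VEGF vehicle gave 341, of the 24 h PDGF vehicle 175, of the 48 h VEGF vehicle 186 and of the 48 h PDGF vehicle 203, and leaving out replicate 2 of the 48 h VEGF vehicle gave 366.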

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

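The comparison of spike-in levels and the list tests of the difference between the factors were chosen after the arrays had been seen.

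Probe sets for control transcripts gave a signal outside the comparisons of genes. On the 72 h PDGF array of replicate 2 the 12 probe sets of the poly-A spike-ins, added before labelling, had a mean of 8.56, above the highest of the 12 vehicle arrays (7.93; mean 7.72, SD 0.125). Other treated arrays above that vehicle array were replicate 2 of VEGF at 72 h (8.04) and of PDGF at 24 h (7.95). On the 72 h PDGF array of replicate 2 the 7 probe sets of the hybridisation spike-ins had a mean of 10.97, above the highest vehicle array (10.76, with a mean of 10.61 and SD 0.0761). Its 100 ERCC probe sets had a mean of 6.36 against a highest vehicle value of 6.35 (mean 6.30, SD 0.0207). These ERCC levels lie near the lowest value of the data, 5.81, and do not show that ERCC transcripts were added.

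Ribosomal protein genes stood lower in the VEGF effect than in the PDGF effect (median difference -0.06, camera adjusted p = 5.1e-06), and so did oxidative phosphorylation genes (median -0.04, adjusted p = 0.0296). With an estimated correlation both lists had an adjusted p of 0.889, and limma called 0 genes for this difference, with 185 at an unadjusted p under 0.05.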

How the results depend on the processing

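Of the tests here, those with a replicate block within each time and the list tests of the difference between the factors were chosen after the data were seen, and the others were planned.

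The counts of 0 genes for VEGF, for PDGF, for their difference, for the vehicles and for the F tests stayed at 0 in limma under each alternative run, leaving out each array included, except that the block within each time called 3 genes for PDGF at 72 h. For 72 h against 24 h the 3835 calls became 6356 with that block and 8159 with all probe sets tested, where genes count more than once. The block within each time takes differences between the days at each time out of the spread. A time comparison then rests only on the spread between arms of the same day and time, so the 6356 calls are no stronger evidence for time. Leaving out 1 array gave 2990 to 3518.

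For 48 h against 24 h the 573 calls became 1749 with the replicate block, 3283 with the block within each time, 279 with the vehicle arrays alone, 966 with all probe sets, 284 with RIN as a covariate, 2507 on hybridisation day 1 and 1026 on day 2, and 175 to 502 on leaving out 1 array. The block within each time and the fits of 1 day leave differences between the days out of the spread, so their counts hold for these days only. The cause of the changes in count was not tested.

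The number of lists past the threshold changed from 4 for VEGF to 0 with an estimated correlation, 0 with fry and 1 among genes at or above the median level, and to 0 to 7 on leaving out 1 array. For PDGF it changed from 3 to 0 with an estimated correlation, 0 with fry, 8 with the block within each time and 6 among genes at or above the median level, and to 3 to 5 on leaving out 1 array. For 72 h against 24 h it changed from 9 to 2 with an estimated correlation and to 8 to 10 on leaving out 1 array. On leaving out 1 array the median of the VEGF effect ran from -0.131 (without the 48 h VEGF array of replicate 2) to 0.0508 (without that of replicate 1) for the DNA replication genes. For the mitosis genes it ran from -0.154 (without the 24 h VEGF vehicle array of replicate 1) to 0.0265 (without that of replicate 2), and was also positive without the 72 h VEGF array of replicate 2 (0.0185). The cause of these changes was not tested.

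With the replicate block, PDGFA (0.23, adjusted p = 0.0257), BUB1B (-0.51, 0.0318), EPHB3 (0.16, 0.00647) and FCGBP (0.37, 0.00214) passed from 24 to 72 h, as did the immediate-early (0.0134) and p53 (0.0296) lists, both at 0.358 with an estimated correlation and the block. With the block the lists past the threshold rose from 2 to 4 for the difference between the factors (0 with an estimated correlation), and with an estimated correlation those of 72 h against 24 h fell from 2 to 1, as the FOXO targets moved to 0.0655. The block changed no other call of a gene named for VEGF, PDGF or 72 h against 24 h, or of a list averaged over times for either factor alone. Of 420 values for named genes, 406 kept their direction and side of the threshold with a common array median and 396 with RIN as a covariate. With only the arms compared 407 kept both, 3 gained a call and 7 lost it. The difference between the factors needs all arrays, so it has no fit of the arms compared alone and its values are not among these. Signal over background limits dim genes: 16385 genes lay at or below the highest background probe set.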

Other observations

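The tests of the replicates over all groups, of the position at 48 h, of the mitosis genes by replicate and of the stress genes at 48 h were chosen after the result was seen, and the splits of the arrays were planned.

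Immediate-early genes, which growth factors and handling induce within minutes, differed between the replicates. Comparing replicate 2 with replicate 1 over the 12 groups (limma with a term for each group), 22 of the 26 measured members were lower in replicate 2 and 1 was higher (list median -0.35, camera adjusted p = 1.12e-17, adjusted p = 0.00793 with an estimated correlation). EGR1 was lower by -2.70 ± 0.21 (adjusted p = 1.33e-07, mean log2 levels 11.56 in replicate 1 and 8.86 in replicate 2), FOS by -2.52 ± 0.14 (11.73 and 9.21), the MAPK phosphatase DUSP1 by -1.88 ± 0.10 and JUN by -1.12 ± 0.08, each in all 12 groups. The vasoconstrictor gene EDN1 (-1.15 ± 0.04), the YAP target CCN2 (-1.12 ± 0.15), the ERK phosphatase DUSP6 (-0.91 ± 0.08) and IER2 (-0.90 ± 0.07) differed the same way. Averaged over the times, the largest difference of any gene with either factor was smaller than each of these, 0.42 for DDIT4 with PDGF.

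Over all genes 3171 were higher and 1847 lower in replicate 2, 10 of them by more than 2-fold. Among the genes higher in replicate 2 were LOC100507412 (1.70 ± 0.12), the glycolytic PKM (1.03 ± 0.08), the sialic acid synthesis gene GNE (0.87 ± 0.06) and the small GTPase ARL14 (0.81 ± 0.03). The SRF and YAP list was lower (7 of 19 lower, 1 higher, adjusted p = 0.016, adjusted p = 0.415 with an estimated correlation), and so was the Wnt and stem cell list (5 of 18 lower, 0 higher, 0.0426, and 0.143). Signs of RNA quality also differed, but in opposite directions. The 3' minus 5' log2 signal of actin ran from 0.811 to 1.07 in replicate 1 and was mostly higher, from 1.02 to 1.47, in replicate 2. That of GAPDH ran from 0.349 to 0.479 in replicate 1 and was mostly lower, from 0.240 to 0.359, in replicate 2. Replicate and hybridisation day are the same in the labels, and no biological explanation was tested.

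The 48 h arrays stood further along the course from 24 to 72 h in replicate 1 than in replicate 2. On a scale from 0 at 24 h to 1 at 72 h over the called genes, the 4 arrays of replicate 1 had a mean position of 0.676 (SD 0.0595) and the 4 of replicate 2 of 0.351 (SD 0.0382), and since each replicate is 1 hybridisation day these SDs measure only the spread of arms within a day. The difference was 0.313 or more in each of 3 classes of genes by level. This cannot decide on compression of signal on 1 day, as each replicate is scaled by its own 24 and 72 h arrays. A compression that these arrays share would largely cancel. RIN as a covariate left 0.356 (SE 0.0280), which argues against RIN as the whole cause. The 3' minus 5' signals were not tried as covariates. A faster course of the replicate 1 cultures stays open: 7 of 7 called lists stood higher in replicate 1, but they are part of the same called genes and so restate the difference, their arrays overlapped in 3 lists, and the mitosis and ribosomal lists were not tested. No biological explanation was tested, since the replicate is no group of the design.

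The median of the mitosis genes was lower at 72 h than at 24 h in replicate 2 and not in replicate 1. Over the 4 arms the list changed by 0.11 (SD 0.14) in replicate 1 and by -0.77 (SD 0.11) in replicate 2 (SDs over the arms of 1 day), and 30 of 30 members were among the 2128 genes whose change differed between replicates. A day effect shared by all genes of the same level is argued against by size. The median difference was -0.80, while the 5th percentile of 10000 lists matched on level was -0.0798. That 0 of these lists reached -0.80 is no measure of chance. The lists draw genes independently, while the mitosis genes move together and were picked after their values were seen. A day effect on mitosis genes alone is not covered. An equally larger loss of all proliferation genes in replicate 2 is argued against too, as the DNA replication genes differed by -0.0736. The mean level of the list was 10.17 and 10.53 at 24 h and 10.26 and 9.78 at 72 h in replicates 1 and 2, and a difference between the cultures of each day stays open, with no biological explanation tested.

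Stress genes stood higher with PDGF than with its vehicle at 48 h in both replicates (median 0.20, 17 of 24 members higher in both, camera adjusted p = 1.14e-05, adjusted p = 0.234 with an estimated correlation), with SESN2 at 0.81, DDIT3 at 0.64 and TRIB3 at 0.60, none past the threshold, and fry passed 0 lists. Subtracting the slope of 0.0801 on the course from 24 to 72 h left 0.14 (0.17 and 0.13 by replicate). This cannot decide whether PDGF cultures were only further along, as the slope takes all genes to move at 1 pace. At 48 h the called stress genes stood at 0.889 and 0.653 of the course in replicates 1 and 2. All called genes stood at 0.676 and 0.351. An effect of PDGF did not pass in limma by gene, with an estimated correlation or with fry, and stays a hypothesis. The shift cannot be told apart from differences between cultures of any pair of arms: of 18 pairs of arms over the 3 times only this 1 was as large in both replicates, and it was picked for its size. Against the VEGF vehicle at 48 h the PDGF arrays also stood higher, as that vehicle differed from them by -0.155 and -0.151, but the VEGF arrays differed from them by 0.09 and -0.22 in replicates 1 and 2.

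Other assignments of the arrays were compared with the real one. For the factors, the arms were swapped within pairs of 1 time and replicate, so that every assignment parts all 6 pairs. Chance could not be excluded for the genes at an unadjusted p under 0.05 with VEGF (362, highest other 1530, 18 of 32 as large) or PDGF (215, highest other 701, 24 of 32), for the lists with VEGF (4, highest other 10, 15 of 32) or PDGF (3, highest other 3, 9 of 32), for the difference between the factors (185, highest other 1047, 31 of 32) or for the vehicles (161, highest other 574, 31 of 32). Some assignments gave several times the real count. Whether this reflects a structure of the arrays that the arms do not follow was not tested.

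For time, the 8 vehicle arrays of both times were split into 4 and 4 in 35 ways. In a fit of 2 groups the real split called 4079 genes for 72 h against 24 h and 776 for 48 h against 24 h. The highest other split called 0 in both (1 of 35 each). Every other split holds both times in each group, so a change with time adds to its spread and holds down its calls. The split by hybridisation day also called 0, and it too holds both times in each group. This does not mean that the days were alike: with a term for each group, 3171 genes were higher and 1847 lower in replicate 2. Only 8 of the 35 part as many pairs, too few for a share under 0.05, and the highest of the others among them called 0. These splits therefore cannot exclude chance for the gene counts. Chance could not be excluded for the count of 9 lists from 24 to 72 h (7 of 35 as large, highest other 11, and 10 among the 8 that part as many pairs), while the split by day gave 2 lists.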
